A study of Mus musculus with 10 samples.

How the data were processed

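Total RNA of 10 samples of mouse left atrial appendage cells was made into libraries with an Illumina TruSeq RNA kit, which does not mark strand, and sequenced. The 5 cell types were taken from the sample titles, with 2 samples each, and the replicate numbers from the same titles. According to the labels, tissue from animals of 8 to 12 weeks was digested in 3 steps of 5 min with trypsin at 0.25% for A or 0.05% for B and with collagenase D at 0.1%.

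The aligner TopHat, the count package DESeq and the mouse genome build mm10 are named, per the submitters' processing notes as held here, with no version, role or order. The read counter, the gene annotation and the settings are not given in the sources used here. The deposited table holds 36172 genes with their Entrez identifiers, and its values are on a log2 scale. What was done to them is not given in the sources used here and was inferred from the values as deposited. They were read as the log2 of a read count divided by a size factor of the library, with values under 1 raised to 1, minus the median of that gene over the 10 libraries. Because only part of the low values fell on whole reads, as given below, this reading is not certain, and the depths, floors and limits rest on it. The median was 0 within 1e-05 for 17821 of 17821 genes with values, and 18334 genes were 0 in every library. In 17 genes 1 cell, and for 1 gene the symbol, had been turned into a date by a spreadsheet, and the 17 genes with such a cell were left out. Because the median was taken away, the level of a gene is known only where at least 2 libraries share its lowest value, which marks the floor of 1 normalized read. This held for 4762 genes with values. For some other genes the level could be inferred for the text, where the lowest library was taken at the floor or at 1 read and both libraries of the lower type then lay at the floor or within 0.002 of whole reads. For the rest only differences between libraries are known, and a normalized value computed from the lowest library is a lower bound.

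Relative depth was found from the spacing of low values. In a library 1 read is worth 1 fixed normalized value, from 0.199 in the deepest C3 library to 2.29 in the shallowest B library, and its inverse is the size factor used as relative depth. The procedure was tested on simulated data of 4000 genes, in which the spacing was recovered for 10 of 10 libraries. The simulation used the depths found here. It held a markedly smaller share of fractional values than C1 replicate 2, where 52.7% of low values were whole, and both C3 libraries, where 43.7% and 32.9% were. It therefore does not test the depths of C1 replicate 2 and C3. Of the low values, up to 20 reads, between 32.9% and 73.2% per library lay within 0.01 of a whole read. Whole reads could therefore not be recovered for nearly all genes, and no test on counts was run. The total number of reads per library is unknown. The limit that a count of 0 allows was taken as 3 reads of the library in question. For a cell type, the mean over its libraries was set against the higher of their limits. A single library of such a type can therefore lie above its own limit.

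Genes were kept where at least 2 libraries reached 10 normalized reads, a filter that can act only on genes with a known level. It removed 3567 genes and left 14254 for testing, of which 1195 have a known level and 13059 do not. limma (version 3.58.1, R 4.3.3) was fitted to the log2 values of all 10 libraries with a mean per cell type, which leaves 5 residual degrees of freedom. The spread was shared between genes by empirical Bayes, with 1.93 prior degrees of freedom and a prior SD of 0.211. Tests were two-sided and adjusted by the Benjamini-Hochberg method within each of 6 comparisons. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The test departs from the one planned before the data were examined in the following points. The trend of the spread with expression level was not modelled, because the level is removed from the values. No pseudocount was added, where 1 had been planned, because the values were already logarithms. The filter was planned for all genes.

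Gene lists of cell types and cell states were fixed before the data were examined, 33 in number. Of these, 26 had at least 5 measured members and were tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over all 156 tests. Another 5 lists were too small, 1 list, of transcripts encoded in mitochondria, had 0 members in the table, and the genes on sex chromosomes served as a check of the labels. In addition, camera was run with a correlation estimated per list, of which the median was 0.236, and with fry, which asks whether the members of a list move, on balance, one way. The correlation was estimated over all 10 libraries and is the same in every comparison of a list. For the macrophage and monocyte list, at 0.750, it includes the gap between the A libraries, even in comparisons without A. Genes named in the text were chosen by a rule fixed at the same time. It takes, whatever their result, the genes of both sort markers and Csf1r, Col1a1, Acta2, Tnnt2, Gata4, Nkx2-5, Nanog and Pou5f1. It adds, per comparison, the 8 largest rises and 8 largest falls among called genes whose replicate ranges do not overlap and whose mean in the higher type is at least 200 normalized reads, and up to 4 called members with the largest difference of each list described. For genes of unknown level, the 200 reads were judged from the lower bound. Not every gene that the rule takes is reported here. Genes in the closing part that fall outside this rule were chosen after their values were seen.

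The test was tried on simulated values for 14254 genes with the spread of the real libraries, in which 200 genes were changed. The spread of a type was scaled by the same factor for all genes. Far more genes were called in the real comparisons, so the counts of unchanged genes called here do not give the number of false calls there. Between 84% and 89% of changes of log2 3 were recovered in the 6 comparisons, and between 50% and 67% of changes of log2 1.5. Unchanged genes were called 76 times for B against A and 62 times for C1 against A, but between 1 and 5 times in the other comparisons. The A libraries differ from each other more than those of other types, and a spread shared by all types is too small for them, so that the calls of both comparisons with A hold more false ones than the adjusted p states. A fit on the 4 libraries compared stands beside these counts for that reason.

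Alternatives to the processing were planned before the data were examined or, where stated in the closing part, added later. They cover the filter on low values, quantile normalization, the threshold, the samples in the fit, the replicate number as a block and leaving out each library in turn. Quantile normalization was run on the values with the gene medians already taken away. It gives every library the same distribution of deviations from those medians, and shrinks large deviations in a library that has many. Its results are therefore no ordinary check of the scaling between libraries. Where 1 library of a type was left out, the other was assumed to vary like the libraries of the other types. Gene positions are from a RefSeq gene table of build GRCm38, on which 14132 of 14254 genes were found by Entrez identifier. Genes with near-identical copies or from multigene families can share reads, and their values are uncertain. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.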

Results

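RNA sequencing measured gene expression in 10 libraries of cells grown from the left atrial appendage, a pouch of the left atrium, of adult C57BL/6 mice aged 8 to 12 weeks. There were 5 cell types with 2 libraries each. A and B were primary cells that grew out after tissue pieces had been treated with trypsin and collagenase D. A came from strong digestion with 0.25% trypsin and was sorted as positive for c-kit, a receptor carried by many stem and progenitor cells, and negative for CD45, the surface protein of white blood cells. B came from weak digestion with 0.05% trypsin and was sorted as positive for both. C1, C2 and C3 were later cultures of B-type cells. C1 was taken at passage 6 and was c-kit positive and CD45 negative, C2 at passage 8 and C3 at passage 10, and both of these were negative for c-kit and CD45. The study asked how the primary types differ and how B-type cells change in culture as they turn into other cell types. Nothing in the labels says that the 2 libraries of a type came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

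The deposited values were on a log2 scale and were read here as read counts per gene, scaled to each library's size, with each gene's median over the 10 libraries taken away. No source used here states this, and between 32.9% and 73.2% of low values per library fell on whole reads. Total reads per library were not used here, but the spacing of low values gave relative depth, on which the deepest library exceeded the shallowest by 11.5 times. The factor was 0.595 and 0.522 in the A libraries, 0.436 and 0.552 in B, 0.992 and 1.498 in C1, 0.490 and 0.966 in C2 and 3.86 and 5.03 in C3. C3 was thus 7.96 times as deep as A and 6.11 times as deep as C2 on average, and genes of low expression were resolved best there. On the same reading, values under 1 normalized read had been raised to 1, which is called the floor below. For a library in which a gene had no read, the limit of 3 reads lay between 5.04 and 6.88 normalized reads in A and B, between 2.00 and 3.02 in C1, at 6.12 and 3.11 in C2, and under the floor in C3. These limits rest on that reading and cover counting error only. Of the 36172 genes listed, 14254 were tested. Values written with ± are log2 differences, the type named first minus the other, with their standard error from limma over 2 libraries per type. That error rests on a spread shared by all 10 libraries and is the same in every comparison of a gene. Where the A libraries differ, it includes their gap even in comparisons without A. A gene is said to have risen or fallen where its adjusted p was under 0.05 and its difference at least 1 on the log2 scale. Where the lower type was known to lie at or under its limit of 3 reads, normalized values stand in place of a difference. For this the mean of the type was set against the higher limit of its 2 libraries, so 1 of them can lie above its own. For genes whose level the table does not give, this could not be told.

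Libraries of 1 type resembled each other more than any library of another type. The root mean square log2 difference over all tested genes was 0.52 within B, 0.49 within C1, 0.52 within C2 and 0.43 within C3, but 1.06 within A. Between types it was lowest for C1 and C2, at 1.33, and its mean was highest for B and C3, at 2.43. The replicates were also compared on genes of known level that reached a minimum of reads in both libraries, among them genes abundant in B. The chi-square per gene between the 2 B libraries was 1.40 over 690 genes, where 1 is due to sampling (chi-square p = 1.18e-11). They therefore differed by little more than sampling noise. They were kept as 2 replicates in the fit, but so small a difference does not show that they came from separate animals or cultures. The same value was 29.9 in A, 4.39 in C1, 1.61 in C2 and 13.0 in C3. Where replicates vary beyond sampling it grows with the number of reads. Depth and the genes used differ between types, so these values do not rank the types.

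The genes of both sorting markers were read first as a check of the labels. Ptprc, which encodes CD45 (chromosome 1, 138062859 to 138175756, build GRCm38), stood at 2773 normalized reads in B, at 44.4 in A, and at the floor or at 1 read in every C library. Its 2 A libraries differed, with centred log2 values of 2.74 and 6.35 against 11.46 and 11.41 in B. Kit, which encodes c-kit (chromosome 5, 75574987 to 75656722), was low throughout. Its centred log2 values were -0.96 and 3.47 in A, 1.81 and 0.96 in B and 2.43 and 3.35 in C1, while C2 stood at the floor of -2.71 and at -1.07, and both C3 libraries lay at that floor. Kit did not pass the test between A, B and C1, and its values in A went to both sides of those in B. Both C1 values lay above both B values, in a fit whose shared spread includes the gap between the A libraries, and in a fit on the 4 libraries of B and C1 alone Kit did not pass either (limma adjusted p = 0.0665). Some alternatives given below called it. Nkx2-5 and Nanog lay below the filter on low values and Pou5f1 was listed at 0 in every library. The first regulates heart muscle and the others pluripotency.

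The genes of sex chromosomes differed between cultures of 1 stated lineage. Ddx3y, a Y-linked RNA helicase (chromosome Y, 1260715 to 1286628), had 486 normalized reads in A, 485 in B, 1296 in C1 and 71.7 in C2, and was at the floor in both C3 libraries. Eif2s3y, Kdm5d and Uty, also on the Y chromosome, followed the same order from 802, 389 and 190 normalized reads in C1 to 48.1, 42.6 and 24.0 in C2 and the floor in C3. Xist, the RNA that silences an X chromosome (chromosome X, 103460373 to 103483233), fell from B to C1 with -9.86 ± 0.89, did not pass between C1 and C2 (-0.17 ± 0.89, limma adjusted p = 0.916) and rose from C2 to C3 with 5.21 ± 0.89 (limma adjusted p = 0.00370). From C1 to C3 its difference was 5.03 ± 0.89. This standard error is shared by all comparisons of Xist, whose SD was 2.14 in A against 0.13, 0.30, 0.84 and 0.24 in B, C1, C2 and C3. The level of Xist in C3 was 3.51% of that in B, whose libraries also held Y-linked transcripts. Because the library kit does not mark strand, reads of Xist and of its antisense partner Tsix cannot be told apart.

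**Figure D1:**
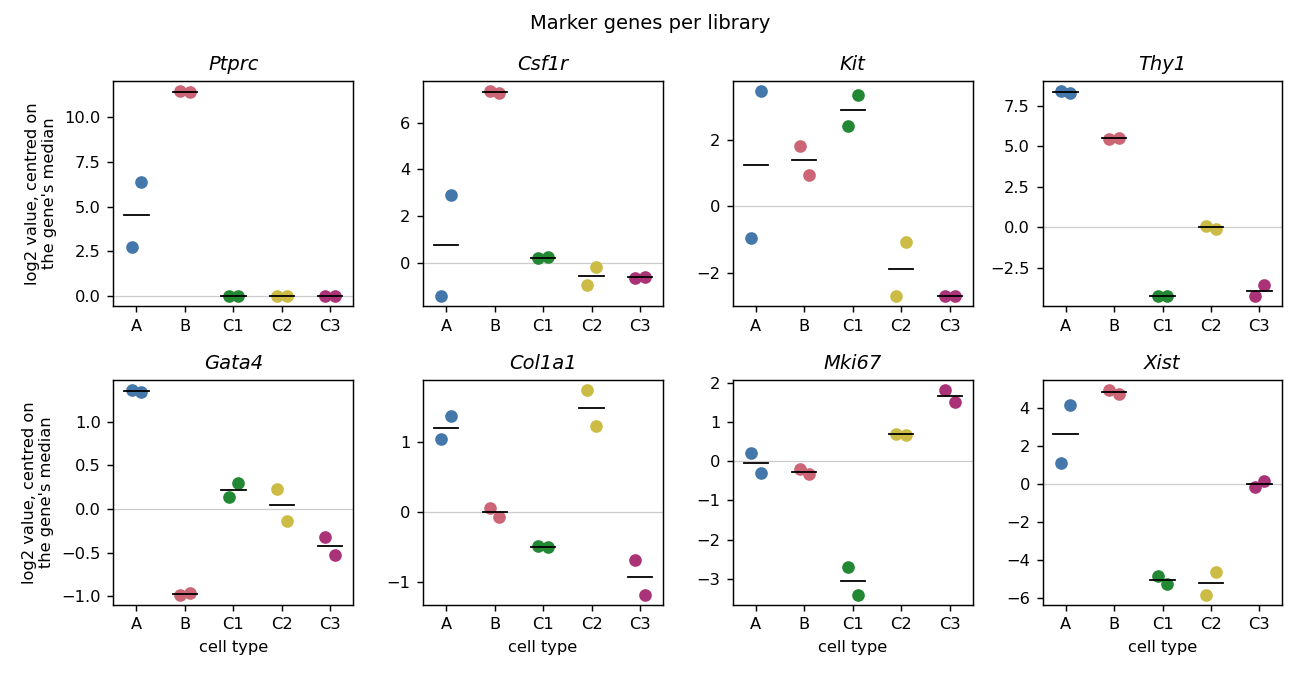
Centred log2 values of 8 genes in the 5 cell types, where each point is a library, the bar is the mean of the 2 libraries, and 0 is the gene's median over all 10. Ptprc reached 11.46 and 11.41 in B and lay near 0, its floor, in every C library, and Kit was at its floor of -2.71 in both C3 libraries.

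B was compared with A to ask how the cells released by weak digestion differ from those released by strong digestion. B was also sorted as CD45 positive and A as CD45 negative, so digestion and sort cannot be separated in this comparison. B cells carried high levels of genes of macrophages, the phagocytes that reside in tissue, and A cells more transcripts of fibroblasts, the cells that build connective tissue. Csf1r, the receptor for the main macrophage growth factor (chromosome 18, 61105572 to 61131139), was higher in B by 6.56 ± 1.19 (limma adjusted p = 0.00491), and Ptprc by 6.88 ± 0.98 (adjusted p = 0.00186). Gata4, a transcription factor of heart development (chromosome 14, 63198914 to 63271712), had -2.33 ± 0.16 (adjusted p = 0.000134), and Thy1, a surface protein of stromal cells (chromosome 9, 44043384 to 44048579), -2.83 ± 0.22, so both fell in B. Col1a1, the chain of the main collagen of connective tissue (chromosome 11, 94936224 to 94953042), also fell, with -1.21 ± 0.24.

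In the macrophage and monocyte list, of 30 measured members 29 rose and 1 did not pass, as they did adjusted over the list alone (camera adjusted p = 4.47e-11; adjusted p = 0.472 with an estimated correlation). Emr1, a macrophage surface protein, stood at 11673 normalized reads in B and 96.3 in A, and Tyrobp, an adaptor of immune receptors, at 8174 and 56.0. In the list of genes shared by all white blood cells, of 21 measured members 21 rose, as they did adjusted over the list alone (camera adjusted p = 5.01e-09; adjusted p = 0.472 with an estimated correlation). Cd52 had 1043 normalized reads in B and 13.0 in A. The size of these differences depended on the A library. Without A replicate 1 the difference was 5.08 for Ptprc, 4.39 for Csf1r, 5.96 for Emr1, 6.23 for Tyrobp and 5.38 for Cd52. Without A replicate 2 it was 8.69 for Ptprc and 8.73 for Csf1r, whose level is unknown, while Emr1, Tyrobp and Cd52 lay at or under the limit of 3 reads in A replicate 1. Across both lists 47 of 50 genes were higher in A replicate 2 than in A replicate 1. A fit on the 4 libraries alone ended the calls of Csf1r (adjusted p = 0.0774) and Ptprc (adjusted p = 0.0536), as did quantile normalization, with differences of 3.19 and 2.29. Quantile normalization was run on the centred values and forces the same distribution of deviations on every library. It can by itself shrink large differences such as these.

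In the antigen presentation list, of 13 measured members 9 rose, 1 fell and 3 did not pass, while 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000957; adjusted p = 0.528 with an estimated correlation). The antigen presentation call was lost under quantile normalization (0.072), where the value in brackets is the camera adjusted p. Cd74, the chaperone of class II molecules, had 329 normalized reads in B and lay under the limit of 3 reads in A, as did the costimulatory gene Cd86 with 216 in B, and the class II chain H2-Aa had 86.2 in B and was at the floor in A. In the inflammatory cytokine list, of 21 measured members 11 rose, 1 fell and 9 did not pass, while 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.472 with an estimated correlation). The cytokine call was lost under quantile normalization (0.0519). The chemokine Ccl12 had 699.7 normalized reads in B and 7.8 in A. Its difference of 7.17 ± 0.83 became 5.64 without A replicate 1, and in A replicate 1 itself it lay under the limit of 3 reads. In the lysosome list, of 21 measured members 20 rose and 1 did not pass, as they did adjusted over the list alone (camera adjusted p = 1.07e-10; adjusted p = 0.464 with an estimated correlation). The protease Ctsd had 4.21 ± 0.27 and the protease Ctsb 3.84 ± 0.32. In the adipocyte list, of 7 measured members 5 rose and 2 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.472 with an estimated correlation). The adipocyte call was lost without A replicate 1 (0.051), C2 replicate 1 (0.0646) or C2 replicate 2 (0.0624) and under quantile normalization (0.066). The fatty acid carrier Fabp4 rose by 4.29 ± 0.36 and the regulator Pparg by 2.42 ± 0.20, both of which macrophages can also express. In the epicardial and mesothelial list, of 14 measured members 7 rose, 1 fell and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.385 with an estimated correlation). The epicardial call was lost without A replicate 2 (0.0828), B replicate 2 (0.0725), C2 replicate 1 (0.0544) or C2 replicate 2 (0.0525). The surface genes Upk3b, Msln and Gpm6a rose by 5.41 ± 0.20, 4.26 ± 0.44 and 4.19 ± 0.21.

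Genes of connective tissue and heart development were lower in B. In the fibroblast and matrix list, of 36 measured members 24 fell and 12 did not pass, while 26 fell adjusted over the list alone (camera adjusted p = 9.98e-09; adjusted p = 0.417 with an estimated correlation). Among these were the growth factor receptor Pdgfra with -2.29 ± 0.23, the microfibril gene Fbn1 with -2.23 ± 0.23, the procollagen enhancer Pcolce with -2.40 ± 0.23 and the transcription factor Twist1 with -2.42 ± 0.20. In the cardiac transcription factor list, of 15 measured members 1 rose, 8 fell and 6 did not pass, while 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.00064; adjusted p = 0.323 with an estimated correlation). Gata4 was among these, as were the homeobox genes Meis1 with -2.25 ± 0.19 and Meis2 with -1.95 ± 0.15. In the list of regulators of epithelial-mesenchymal transition, of 17 measured members 1 rose, 10 fell and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.472 with an estimated correlation). Twist2 had -2.92 ± 0.22 and Zeb1 -2.03 ± 0.12. In the smooth muscle and contractile list, of 16 measured members 1 rose, 7 fell and 8 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.385 with an estimated correlation). The contractile call was lost without A replicate 2 (0.0612). The cytoskeletal gene Smtn had -2.10 ± 0.23, the receptor Notch3 -2.06 ± 0.40 and tropomyosin Tpm2 -1.62 ± 0.20. The cell cycle list was called downwards although few members moved: of 28 measured members 1 rose, 2 fell and 25 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0269; adjusted p = 0.763 with an estimated correlation). The cell cycle call was lost without A replicate 1 (0.133) and by fry (0.148). The replication clamp Pcna rose by 1.30 ± 0.22. The cardiomyocyte list was not called: of 11 measured members 2 rose and 9 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.678). Neither was the endothelial list: of 15 measured members 3 rose, 3 fell and 9 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.943). In the haematopoietic progenitor list, of 11 measured members 6 rose, 2 fell and 3 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.178), and in the pluripotency list, of 8 measured members 2 fell and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.401).

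Among single genes, the 8 largest rises were Arg1, Mmp12, Wfdc17, Cd36, Ms4a6d, Cd84, Fcer1g and Tyrobp, all known from macrophages or other myeloid cells. Arg1, arginase 1, rose most with 9.67 ± 1.94, which became 6.25 without A replicate 1, the library in which it lay under the limit of 3 reads, and a fit on the 4 libraries alone ended its call (adjusted p = 0.0865). Among the largest falls, the basement membrane collagen Col15a1 had -5.16 ± 0.34 and the angiotensin-converting enzyme Ace -4.52 ± 0.36, and the tetraspanin Tspan11 had 219 normalized reads in A and lay under the limit of 3 reads in B. Tnnt2, a cardiac troponin, did not pass (1.83 ± 1.16, adjusted p = 0.251), and its value without A replicate 2 was 3.72 and called. Kit did not pass either (0.13 ± 1.32, adjusted p = 0.951), while it passed upwards without A replicate 2, where the remaining A library lay under the limit of 3 reads, and stood at -2.09 without A replicate 1. Over all genes limma called 2066 as higher and 1769 as lower in B, 3835 in all, against 2538 when fitted on the 4 libraries alone. Under quantile normalization, which makes the deviations of all libraries alike in distribution, 1484 were higher and 1714 lower, so the majority turned. In simulated values of this comparison with 200 changed among 14254 genes, 76 of the unchanged genes were called. With 3835 genes called in the real values, that count does not carry over to them. Quantile normalization moved 58 of 121 named genes by more than 1.5 times and ended the calls of 30.

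C1 was compared with B to ask what changed between the primary CD45-positive cells and their culture at passage 6. C1 was also sorted as CD45 negative, so culture and sort cannot be separated in this comparison, least of all for genes of white blood cells. Genes of white blood cells fell in C1. Ptprc fell from 2773 normalized reads in B to the floor or 1 read in C1 (limma adjusted p = 0.000152), and Csf1r fell with -7.09 ± 1.19 (adjusted p = 0.00258). Thy1 also fell, from 849 normalized reads in B to under the limit of 3 reads in C1 (adjusted p = 1.03e-06). Gata4 rose by 1.20 ± 0.16 (adjusted p = 0.0011) and its partner in heart development Meis2 by 2.61 ± 0.15. Kit did not pass, with 1.51 ± 1.32 (adjusted p = 0.372) in the fit as planned and 3.79 under quantile normalization, which called it.

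In the macrophage and monocyte list, of 30 measured members 30 fell, as they did adjusted over the list alone (camera adjusted p = 5.85e-11; adjusted p = 0.472 with an estimated correlation). The Fc receptor gene Fcgr2b and Tyrobp went from 10521 and 8174 normalized reads in B to under the limit of 3 reads in C1. In the list shared by white blood cells, of 21 measured members 21 fell, as they did adjusted over the list alone (camera adjusted p = 1.66e-08; adjusted p = 0.472 with an estimated correlation). The lysosomal membrane gene Laptm5 had -11.67 ± 1.22 and the lipid phosphatase Inpp5d went from 2641 normalized reads in B to under the limit of 3 reads in C1. In the antigen presentation list, of 13 measured members 11 fell and 2 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000153; adjusted p = 0.472 with an estimated correlation). The integrin Itgax went from 4662 normalized reads in B to under the limit in C1. In the inflammatory cytokine list, of 21 measured members 1 rose, 16 fell and 4 did not pass, while 1 rose and 17 fell adjusted over the list alone (camera adjusted p = 0.000144; adjusted p = 0.472 with an estimated correlation). Ccl3 had 698 normalized reads in B and lay under the limit in C1. In the lysosome list, of 21 measured members 11 fell and 10 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000285; adjusted p = 0.562 with an estimated correlation). The lysosome call was lost under quantile normalization (0.669). Ctsd had -4.57 ± 0.27 and the protease Lgmn -3.01 ± 0.19. In the adipocyte list, of 7 measured members 4 fell and 3 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.472 with an estimated correlation). The adipocyte call was lost without C2 replicate 1 (0.0534) or C2 replicate 2 (0.0515). Fabp4 had -7.60 ± 0.36 and the transcription factor Cebpa -5.57 ± 0.33.

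Genes of oxygen response, proliferation and vessels fell as well. In the hypoxia and glycolysis list, of 18 measured members 16 fell and 2 did not pass, as they did adjusted over the list alone (camera adjusted p = 3.95e-07; adjusted p = 0.385 with an estimated correlation). Ankrd37 had -6.28 ± 0.33, the carbonic anhydrase Car9 -4.23 ± 0.54 and the stress gene Ndrg1 -3.47 ± 0.46. In the cell cycle list, of 28 measured members 17 fell and 11 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000121; adjusted p = 0.562 with an estimated correlation). The proliferation marker Mki67 had -2.78 ± 0.27, the centromere histone Cenpa -3.46 ± 0.15, the mitotic kinase Plk1 -2.64 ± 0.34 and the cyclin Ccna2 -2.60 ± 0.23. In the endothelial list, of 15 measured members 2 rose, 10 fell and 3 did not pass, while 2 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.562 with an estimated correlation). The junction genes Cdh5 and Pecam1 had 38.9 and 33.5 normalized reads in B and lay under the limit of 3 reads in C1, as did the junction gene Esam with 58.2 in B. In the list of stem and progenitor surface genes, of 16 measured members 2 rose, 9 fell and 5 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.385 with an estimated correlation). The surface gene call was lost without A replicate 1 (0.0791) or A replicate 2 (0.0828). The adhesion molecule Alcam had 2117 normalized reads in B and lay under the limit of 3 reads in C1. In the immediate early list, of 17 measured members 10 fell and 7 did not pass, while 11 fell adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.562 with an estimated correlation). Egr2 had -3.16 ± 0.59. In the cholesterol and lipid efflux list, of 17 measured members 8 fell and 9 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0496; adjusted p = 0.627 with an estimated correlation). The cholesterol call was lost without B replicate 1 (0.0702), B replicate 2 (0.0626), C1 replicate 1 (0.166), C2 replicate 1 (0.0588) or C2 replicate 2 (0.0568) and under quantile normalization (0.0804). The lipid carrier Apoe, abundant in macrophages, fell with -5.29 ± 0.22 and the synthesis gene Dhcr7 with -2.60 ± 0.44. In the neural and Schwann cell list, of 8 measured members 5 fell and 3 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.385 with an estimated correlation). The neural call was lost without B replicate 2 (0.0539), C2 replicate 1 (0.0558) or C2 replicate 2 (0.0538). The receptor Ngfr had 80.1 normalized reads in B and was at the floor in C1. The fibroblast and matrix list moved both ways and was not called: of 36 measured members 11 rose, 8 fell and 17 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.838). The matrix protein Thbs2 had 5.48 ± 0.29 and Postn -3.30 ± 0.38. The senescence and p53 target list was not called: of 16 measured members 8 fell and 8 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.243), and in the bone and cartilage list of 7 measured members 1 rose, 3 fell and 3 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.611).

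The largest rises included 4930486L24Rik with 6.95 ± 0.26, Thbs2, the membrane protein Vat1l with 5.45 ± 0.46 and Pax3, a regulator of muscle and neural crest precursors, with 7.53 ± 1.19. The value of Pax3 was 5.35 without B replicate 2, the library with its lowest value, and larger without B replicate 1. The cardiac and vascular transcription factor Mef2c had 672 normalized reads in B and lay under the limit of 3 reads in C1. The cardiac transcription factor list was not called: of 15 measured members 4 rose, 3 fell and 8 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.799). Col1a1 (-0.49 ± 0.24, adjusted p = 0.133) and the smooth muscle actin Acta2 (0.43 ± 0.29, adjusted p = 0.252) did not pass, nor did Tnnt2 (0.81 ± 1.16, adjusted p = 0.59), which stood at -0.07 without C1 replicate 1. limma called 1799 genes as higher and 3005 as lower in C1, so 37.4% of calls were higher, against 50.6% under quantile normalization. That setting moved 91 of 132 named genes by more than 1.5 times and ended the calls of 7, and Csf1r then stood at -3.38 and Thbs2 at 7.76.

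C1 and A carry the same sorting markers and were compared to ask how alike the c-kit positive, CD45 negative cells of either source are. They differed in 3798 genes. Most measured members of the matrix, endothelial and cell cycle lists were lower in C1, though 2 matrix genes rose. The calls of these lists were lost with an estimated correlation (camera adjusted p = 0.472 for each). Thy1 had 6047 normalized reads in A and lay under the limit of 3 reads in C1 (limma adjusted p = 1.54e-06). The matrix protein Postn fell in C1 with -5.01 ± 0.38, Col1a1 with -1.70 ± 0.24 (adjusted p = 0.00198) and Gata4 with -1.13 ± 0.16 (adjusted p = 0.00213). Kit did not pass, with 1.63 ± 1.32 (adjusted p = 0.346), and its values in A and C1 were -0.96 and 3.47 against 2.43 and 3.35. It was called higher in C1 without A replicate 2, with A replicate 1 under the limit of 3 reads, and under quantile normalization, at 3.82.

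In the fibroblast and matrix list, of 36 measured members 2 rose, 20 fell and 14 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000178; adjusted p = 0.472 with an estimated correlation). The gelatinase Mmp2 had -4.34 ± 0.34 beside Postn. In the stem and progenitor surface list, of 16 measured members 10 fell and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000913; adjusted p = 0.323 with an estimated correlation). Alcam had 134 normalized reads in A and lay under the limit of 3 reads in C1. In the cell cycle list, of 28 measured members 19 fell and 9 did not pass, as they did adjusted over the list alone (camera adjusted p = 1.5e-08; adjusted p = 0.472 with an estimated correlation). Plk1 had -3.60 ± 0.34, the mitotic activator Cdc20 -3.35 ± 0.33 and Ccna2 -3.27 ± 0.23. In the hypoxia and glycolysis list, of 18 measured members 13 fell and 5 did not pass, while 14 fell adjusted over the list alone (camera adjusted p = 5.84e-07; adjusted p = 0.385 with an estimated correlation). Ankrd37 had -3.65 ± 0.33 and the glucose transporter Slc2a1 -2.87 ± 0.22. In the endothelial list, of 15 measured members 8 fell and 7 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.00228; adjusted p = 0.472 with an estimated correlation). Cdh5 fell from 38.3 normalized reads in A to under the limit of 3 reads. In the cardiac transcription factor list, of 15 measured members 8 fell and 7 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.385 with an estimated correlation). Mef2c had 182 normalized reads in A and lay under the limit of 3 reads in C1, Tbx2 had -5.15 ± 0.21 and Tbx5 -3.12 ± 0.58. In the immediate early list, of 17 measured members 10 fell and 7 did not pass, while 11 fell adjusted over the list alone (camera adjusted p = 0.000587; adjusted p = 0.472 with an estimated correlation). Egr3 had -3.05 ± 0.19. In the DNA methylation and chromatin list, of 22 measured members 1 rose, 8 fell and 13 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.472 with an estimated correlation). The chromatin call was lost without A replicate 1 (0.125), C1 replicate 2 (0.0527), C2 replicate 1 (0.0533) or C2 replicate 2 (0.0513). Uhrf1, which guides maintenance methylation, had -2.63 ± 0.30 and Dnmt3l -2.04 ± 0.30. The list of regulators of epithelial-mesenchymal transition was called downwards, though few members moved: of 17 measured members 2 fell and 15 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0411; adjusted p = 0.518 with an estimated correlation). The transition regulator call was lost without A replicate 1 (0.183), C1 replicate 1 (0.0573) or C1 replicate 2 (0.0578) and under quantile normalization (0.145). Foxc2 had -3.28 ± 0.38 and Snai1 -1.91 ± 0.27.

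White blood cell genes were lower in C1 than in A where they passed. In the macrophage and monocyte list, of 30 measured members 10 fell and 20 did not pass, while 8 fell adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.806 with an estimated correlation). The macrophage call was lost without A replicate 2 (0.47) and by fry (0.132). In the list shared by white blood cells, of 21 measured members 6 fell and 15 did not pass, while 4 fell adjusted over the list alone (camera adjusted p = 0.0222; adjusted p = 0.763 with an estimated correlation). The pan-leukocyte call was lost without A replicate 2 (0.147) and by fry (0.0942). Ptprc fell from 44.4 normalized reads in A to the floor or 1 read in C1 (adjusted p = 0.00958), and a fit on the 4 libraries alone ended that call (adjusted p = 0.105). Csf1r did not pass, with -0.53 ± 1.19, and it was called higher in C1 without A replicate 2, at 1.64, and lower without A replicate 1, at -2.70. In the lysosome list, by contrast, of 21 measured members 10 rose and 11 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.562 with an estimated correlation). The enzyme Hexa had 2.09 ± 0.23. In the epicardial and mesothelial list, of 14 measured members 6 rose, 3 fell and 5 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.385 with an estimated correlation). The epicardial call was lost without A replicate 2 (0.0812) and under quantile normalization (0.066). The transcription factor Bnc1 rose by 4.61 ± 0.19.

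The largest rises in C1 included 4930486L24Rik with 9.01 ± 0.26 and the acute phase gene Saa3 with 7.75 ± 0.47. Vat1l had 947 normalized reads in C1 and lay under the limit of 3 reads in A, and the amino acid transporter Slc38a5 had 522 normalized reads in C1 and was at the floor in A. The largest falls included Col15a1 with -11.60 ± 0.34. The imprinted growth regulator Grb10 and the mitochondrial gene Ndufa4l2 had 1057 and 2412 normalized reads in A and lay under the limit of 3 reads in C1. limma called 1433 genes as higher and 2365 as lower in C1, so 37.7% of calls were higher, against 51.3% under quantile normalization. A fit on the 4 libraries alone called 2375, against 3798 in all. In simulated values of this comparison 62 of the unchanged genes were called. Quantile normalization took Gata4 just under the fold threshold, at -0.996, and moved 27 of 124 named genes by more than 1.5 times, with 3 calls ended.

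C2 was compared with C1 to ask what changed between passages 6 and 8, between which the label turns from c-kit positive to negative. HOX genes, which set position along the body axis, and genes of cell division rose together. Hoxd3 (chromosome 2, 74711993 to 74748271) had 269 normalized reads in C2 and was at the floor in C1, and Mki67 rose by 3.73 ± 0.27 (limma adjusted p = 0.000235). H19, an imprinted long noncoding RNA of fetal tissue (chromosome 7, 142575530 to 142578146), had 3643 normalized reads in C2 and lay under the limit of 3 reads in C1. Col1a1 rose by 1.98 ± 0.24 (adjusted p = 0.00145). Kit fell from 50.8 normalized reads in C1 to at or under the limit of 3 reads in C2 (limma adjusted p = 0.0295). That call was lost when any 1 library of B, C1, C2 or C3 was left out, with an adjusted p from 0.052 without either B library to 0.147 without C2 replicate 1.

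In the HOX list, of 19 measured members 14 rose, 2 fell and 3 did not pass, as they did adjusted over the list alone (camera adjusted p = 6.2e-08; adjusted p = 0.227 with an estimated correlation). The members Hoxa3 and Hoxa5 had 175 and 159 normalized reads in C2 and were at the floor in C1, and Hoxd8 had 231 and lay under the limit of 3 reads in C1. Hoxc6 went the other way, with 20.2 normalized reads in C1 and both C2 libraries at the floor. In the cell cycle list, of 28 measured members 23 rose and 5 did not pass, as they did adjusted over the list alone (camera adjusted p = 2.32e-13; adjusted p = 0.417 with an estimated correlation). Ccna2 had 3.48 ± 0.23, Cenpa 3.42 ± 0.15 and the cyclin Ccnb2 3.13 ± 0.27. In the hypoxia and glycolysis list, of 18 measured members 16 rose, 1 fell and 1 did not pass, as they did adjusted over the list alone (camera adjusted p = 1.93e-08; adjusted p = 0.385 with an estimated correlation). Car9 had 5.10 ± 0.54, Ankrd37 4.78 ± 0.33 and Ndrg1 3.12 ± 0.46. In the DNA methylation and chromatin list, of 22 measured members 11 rose, 1 fell and 10 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000121; adjusted p = 0.385 with an estimated correlation). Uhrf1 had 3.19 ± 0.30 and the histone methyltransferase Ezh2 2.36 ± 0.21. In the epicardial and mesothelial list, of 14 measured members 6 rose and 8 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.00495; adjusted p = 0.385 with an estimated correlation). The keratins Krt7 and Krt18 had 5.00 ± 0.92 and 3.07 ± 0.44 and Lrrn4 2.36 ± 0.18. In the smooth muscle and contractile list, of 16 measured members 6 rose and 10 did not pass, while 8 rose adjusted over the list alone (camera adjusted p = 0.00814; adjusted p = 0.385 with an estimated correlation). The myosin light chain Myl9 had 3.79 ± 0.37 and Lmod1 2.96 ± 0.20. In the immediate early list, of 17 measured members 4 rose and 13 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0496; adjusted p = 0.627 with an estimated correlation). The immediate early call was lost without A replicate 1 (0.0553), A replicate 2 (0.0591), B replicate 1 (0.0624), B replicate 2 (0.0626), C1 replicate 2 (0.302) or C2 replicate 1 (0.157). Egr3 had 2.91 ± 0.19 and Nr4a1 2.57 ± 0.37. The lysosome list fell: of 21 measured members 11 fell and 10 did not pass, while 12 fell adjusted over the list alone (camera adjusted p = 1.09e-07; adjusted p = 0.472 with an estimated correlation). The protease Ctsk had -4.45 ± 0.34, Hexa -2.02 ± 0.23, Lamp1 -1.86 ± 0.20 and Lgmn -1.56 ± 0.19.

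Other lists moved both ways. In the fibroblast and matrix list, of 36 measured members 8 rose, 9 fell and 19 did not pass, while 9 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.386). The transcription factor Tcf21 had -4.07 ± 0.41. In the stem and progenitor surface list, of 16 measured members 7 rose, 3 fell and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0974). Alcam had 244 normalized reads in C2 and lay under the limit of 3 reads in C1, and the endoglin gene Eng had -6.04 ± 0.17. In the senescence list, of 16 measured members 3 rose, 4 fell and 9 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.181). The stress cytokine Gdf15 had -4.50 ± 0.48 and the cell cycle inhibitor Cdkn2b -3.86 ± 0.45. Among the largest rises beside H19 were the imprinted genes Plagl1 and Dlk1 with 9.63 ± 0.40 and 8.97 ± 0.36 and Grb10, which had 1658 normalized reads in C2 and lay under the limit of 3 reads in C1. Among the largest falls, Vat1l had 947 normalized reads in C1 and lay under the limit of 3 reads in C2. Others were the antioxidant enzyme Gpx3 with -8.25 ± 0.16 and the dipeptidase Dpep1 with -6.83 ± 0.17. The Y-linked genes fell here too, Ddx3y with -4.21 ± 0.31 and Eif2s3y with -4.08 ± 0.23. limma called 1740 genes as higher and 1166 as lower in C2, so 59.9% of calls were higher, against 49.2% under quantile normalization. That setting moved 63 of 112 named genes by more than 1.5 times and ended 0 of their calls.

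**Figure D2:**
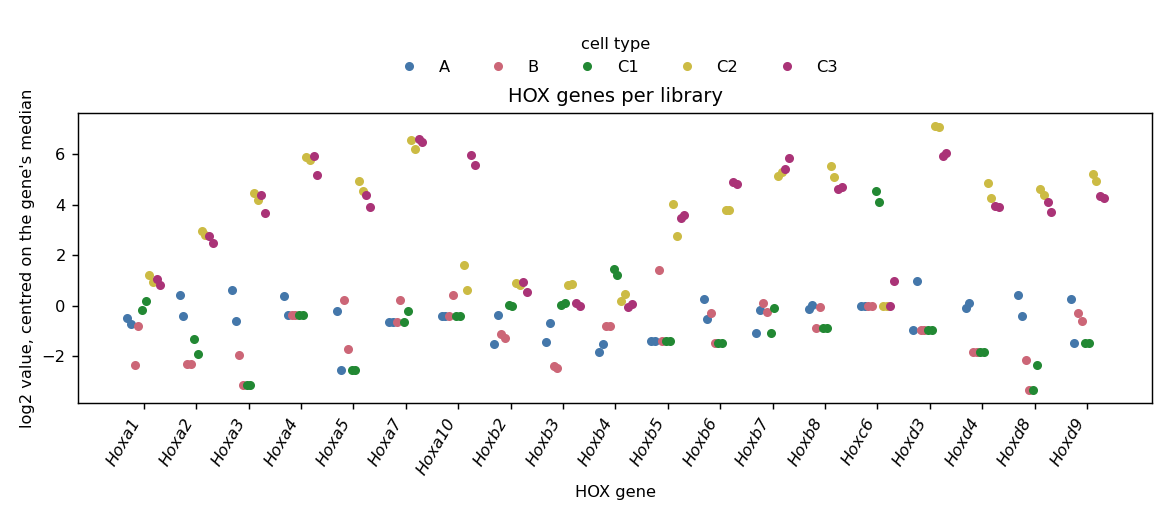
Centred log2 values of 19 HOX genes in each of the 10 libraries, coloured by cell type. Of these genes 14 rose from C1 to C2, and Hoxc6 was above the floor in C1 and at the floor in both C2 libraries.

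C3 was compared with C2 to ask what changed from passage 8 to 10, both c-kit and CD45 negative. Interferon response genes, which defend against viruses, rose in C3, and genes of connective tissue fell. Oas1a, a sensor of double-stranded RNA from a multigene family, rose by 6.81 ± 0.21 (limma adjusted p = 8.13e-06), and Usp18, a brake on interferon signalling, by 6.56 ± 0.41. Col1a1 fell with -2.41 ± 0.24 (adjusted p = 0.000479) and Postn with -6.22 ± 0.38. H19 fell, with -9.83 ± 0.22, and Kit was at the floor in both C3 libraries.

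In the interferon response list, of 18 measured members 17 rose and 1 did not pass, as they did adjusted over the list alone (camera adjusted p = 6.46e-11; adjusted p = 0.385 with an estimated correlation). Oas2 had 5.77 ± 0.39, and Oasl1 had 376 normalized reads in C3 and lay under the limit of 3 reads in C2. Reads of the Oas family can be shared among its members, so the share of each is uncertain. In the cell cycle list, of 28 measured members 22 rose and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 2.97e-09; adjusted p = 0.472 with an estimated correlation). Plk1 had 2.77 ± 0.34, the nucleotide enzyme Rrm2 2.38 ± 0.20, the kinase Aurka 2.10 ± 0.17 and Cdc20 2.00 ± 0.33. In the fibroblast and matrix list, of 36 measured members 3 rose, 28 fell and 5 did not pass, as they did adjusted over the list alone (camera adjusted p = 1.1e-08; adjusted p = 0.417 with an estimated correlation). The collagen chain Col6a3 had -7.67 ± 0.58 and Thbs2 -4.77 ± 0.29. In the cardiac transcription factor list, of 15 measured members 7 fell and 8 did not pass, while 9 fell adjusted over the list alone (camera adjusted p = 0.0095; adjusted p = 0.385 with an estimated correlation). Mef2c had -4.80 ± 0.40, the Notch target Hey1 -3.66 ± 0.63 and Tbx2 -2.94 ± 0.21. In the adipocyte list, of 7 measured members 5 fell and 2 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.00557; adjusted p = 0.472 with an estimated correlation). The lipase Lpl had -5.30 ± 0.33, Fabp4 -3.56 ± 0.36 and Pparg -2.13 ± 0.20. The epicardial list was not called: of 14 measured members 6 rose, 2 fell and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.124), nor was the HOX list: of 19 measured members 1 rose and 18 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.742). Hoxa10 was the member that rose, to 73.7 normalized reads from under the limit of 3 reads in C2.

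The largest rises included Plac9 with 7.63 ± 0.37 and Klra4, from a family of natural killer cell receptors, with 6.73 ± 0.93. Vat1l and the adhesion gene Mpzl2 had 486 and 400.3 normalized reads in C3 and lay under the limit of 3 reads in C2. Plac9 has near-identical copies in the table, Gm9780 and Gm10393, so its reads may be divided between them. The largest falls included Ace with -9.76 ± 0.36, Col15a1 with -8.09 ± 0.34, the imprinted long noncoding RNA Meg3 with -8.08 ± 0.44 and the liver secretory gene Ahsg with -7.90 ± 0.92, and the Wnt antagonist Sfrp2 had 283 normalized reads in C2 and was at the floor in C3. limma called 1657 genes as higher and 2315 as lower in C3, so 41.7% of calls were higher, against 52.7% under quantile normalization. That setting moved 83 of 119 named genes by more than 1.5 times, ended the calls of 8 and took the lysosomal protease Lgmn from -1.26 ± 0.19 to 0.13.

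C3 was compared with C1 for the whole course from passage 6 to 10. C1 was also sorted as c-kit positive and C3 as c-kit negative, so passage and gate cannot be separated in this comparison. At passage 10 most measured members of the cell cycle, interferon response and epicardial and mesothelial lists were higher. Most of the matrix and lysosome lists were lower. The camera calls of these lists were lost with an estimated correlation. The keratin Krt18 rose by 8.64 ± 0.44 (limma adjusted p = 2.09e-05), Plk1 by 5.87 ± 0.34 (adjusted p = 3.18e-05) and Usp18 by 6.51 ± 0.41, while Thbs2 fell with -8.23 ± 0.29. The cell cycle inhibitor Cdkn2a fell with -8.63 ± 0.30 (adjusted p = 5.76e-06). Kit had 50.8 normalized reads in C1 and was at the floor in C3 (adjusted p = 0.0104), a call that was lost without C1 replicate 2 (adjusted p = 0.0583).

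In the interferon response list, of 18 measured members 18 rose, as they did adjusted over the list alone (camera adjusted p = 2.97e-09; adjusted p = 0.385 with an estimated correlation). Oas1a had 6.45 ± 0.21. In the cell cycle list, of 28 measured members 27 rose and 1 did not pass, as they did adjusted over the list alone (camera adjusted p = 8.2e-14; adjusted p = 0.417 with an estimated correlation). Ccna2 had 4.99 ± 0.23, Cdc20 4.93 ± 0.33 and Mki67 4.71 ± 0.27. In the HOX list, of 19 measured members 14 rose, 2 fell and 3 did not pass, as they did adjusted over the list alone (camera adjusted p = 1.55e-05; adjusted p = 0.278 with an estimated correlation). Hoxa7 had 144 normalized reads in C3 and lay under the limit of 3 reads in C1. In the epicardial and mesothelial list, of 14 measured members 8 rose and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000676; adjusted p = 0.323 with an estimated correlation). Krt19 had 7.74 ± 0.82 and Upk3b 5.44 ± 0.20. In the hypoxia and glycolysis list, of 18 measured members 14 rose, 1 fell and 3 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.000121; adjusted p = 0.472 with an estimated correlation). Slc2a1 had 2.92 ± 0.22, the enolase Eno1 2.84 ± 0.21 and the vasodilator peptide Adm -4.11 ± 0.36. In the fibroblast and matrix list, of 36 measured members 2 rose, 19 fell and 15 did not pass, as they did adjusted over the list alone (camera adjusted p = 4.98e-05; adjusted p = 0.472 with an estimated correlation). Fbln1 had -7.04 ± 0.31, Mfap5 -6.85 ± 0.94 and Tcf21 -6.78 ± 0.41. In the lysosome list, of 21 measured members 16 fell and 5 did not pass, as they did adjusted over the list alone (camera adjusted p = 1.4e-06; adjusted p = 0.472 with an estimated correlation). Ctsk had -8.87 ± 0.34, Lgmn -2.83 ± 0.19 and Hexa -2.22 ± 0.23. In the list of regulators of epithelial-mesenchymal transition, of 17 measured members 7 fell and 10 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.472 with an estimated correlation). Twist2 had -4.08 ± 0.22, Foxc2 -3.39 ± 0.38, Prrx1 -2.46 ± 0.23 and Tgfb3 -2.16 ± 0.16. The senescence list was not called: of 16 measured members 5 rose, 4 fell and 7 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.998).

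The largest rises were Krt18, Krt19, the laminin receptor subunit Itga6 with 7.72 ± 0.43 and Klra4 with 7.72 ± 0.93 among others, and the tetraspanin Tspan8 had 879 normalized reads in C3 and lay under the limit of 3 reads in C1. The largest falls included Gpx3 with -10.71 ± 0.16, Glipr1 with -10.17 ± 0.24, Saa3 with -10.03 ± 0.47, the peptidase Naalad2 with -9.17 ± 0.20 and the membrane glycoprotein Emb with -9.11 ± 0.35. limma called 2437 genes as higher and 2529 as lower in C3. Quantile normalization moved 62 of 115 named genes by more than 1.5 times and ended the calls of 6. Over the 6 comparisons camera called 59 of 156 list tests with its preset correlation of 0.01, and 0 with an estimated correlation, where 20 had an unadjusted p under 0.05, while fry called 104.

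**Figure D3:**
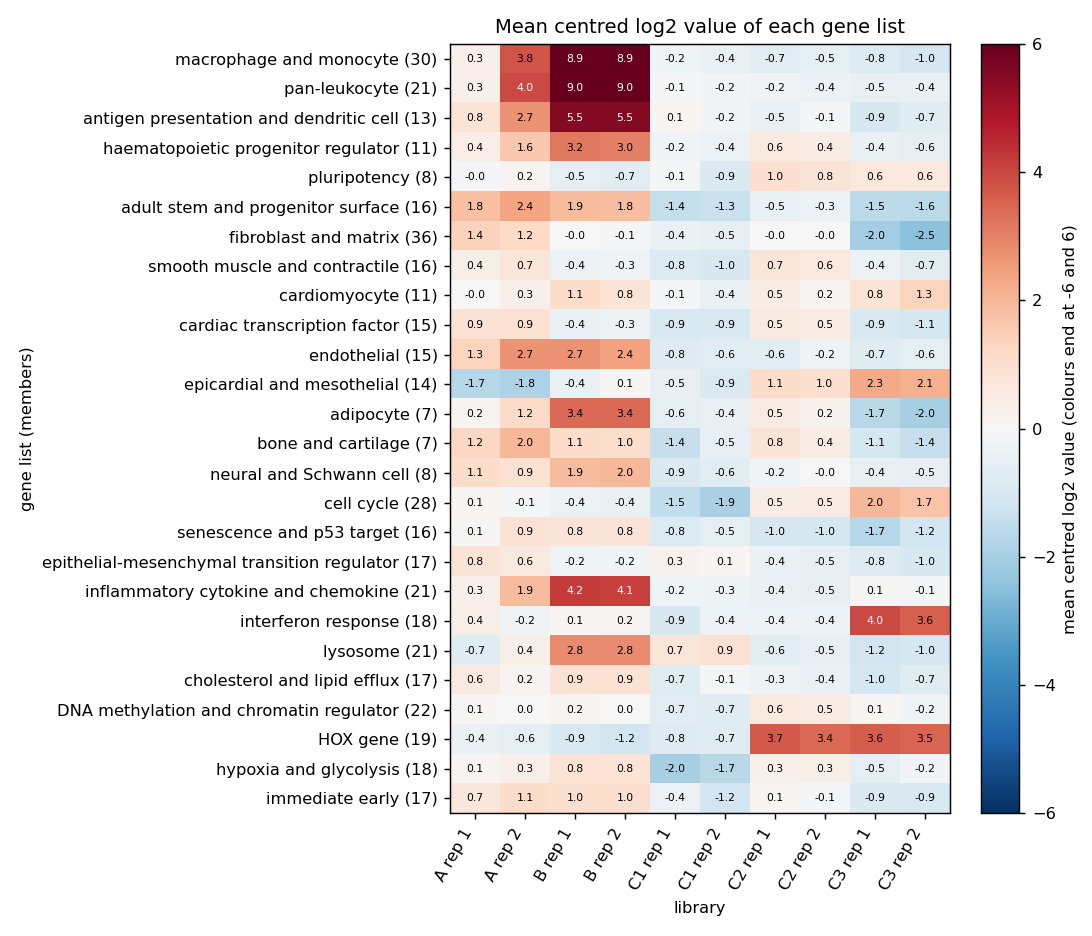
Mean centred log2 value of the measured members of 26 gene lists in each of the 10 libraries, with the number of members in brackets and colours that end at -6 and 6. Macrophage and white blood cell lists are high in both B libraries, HOX genes in C2 and C3, and interferon response genes in C3.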

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

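The alternatives of array weights, a robust prior, a trimmed mean shift and genes with no known floor alone were chosen after seeing the data, and the others before. The counts of called genes stayed within 1.5 times of those reported under every alternative run, except that a fit on the 4 libraries compared gave 2538 for B against A and 2375 for C1 against A, and that an adjusted p without the fold threshold, which admits smaller changes by construction, gave 7337 for C1 against B, 6202 for C1 against A, 5025 for C2 against C1, 6359 for C3 against C2 and 7484 for C3 against C1. Of the 2538 and 2375 genes, 2488 and 2337 were among those reported. Leaving out 1 library at a time gave 3183 to 4299 genes for B against A, 4244 to 5066 for C1 against B, 3103 to 4238 for C1 against A, 2174 to 3298 for C2 against C1, 3249 to 4286 for C3 against C2 and 4448 to 5248 for C3 against C1, and 52 to 65 called lists. Of the 59 list calls, 0 stood with camera's estimated correlation, where 20 of 156 tests had an unadjusted p under 0.05 and the lowest adjusted p was 0.227, while fry called 104, of which 56 were among the 59. Lists with an estimate under the preset 0.01, such as HOX genes at -0.014, lost their calls too. The size of the correlation alone therefore does not account for these losses. Apart from the estimated correlation, 17 of the 59 lost their call under at least 1 setting. Among 723 results of named genes, 3 reversed. Ngfr in B against A went from 2.58 to -0.47 and Lgmn in C3 against C2 from -1.26 to 0.13 under quantile normalization, and Csf1r in C1 against A, -0.53 as reported, ranged from -2.70 to 1.64 when 1 library was left out. The cause was not tested for Ngfr, Lgmn or the smaller counts of the 4-library fits, and Csf1r follows the 2 A libraries, which differ. Over all settings, named genes stayed on their side of the threshold in 12764 cases, 22 of which were values that were not called and changed sign, lost the call in 637 and gained it in 14. The libraries were weighted at 0.347 in A against 1.04 to 1.65 elsewhere by the array weights, with 3375, 5136, 3295, 3220, 4194 and 5249 genes called in the order above. With the replicate number as a replicate block, the counts were 3814, 4774, 3760, 2865, 3937 and 4927 in the same order, with 58 lists. The epicardial list in B against A and the cholesterol list in C1 against B then missed the threshold, both with an adjusted p of 0.0521. The deviations of libraries with the same number correlated between -0.0609 and 0.0893, so the numbers do not pair the samples. The lowest root mean square difference between types was 1.325 with the trimmed mean shift and 1.178 over genes with no known floor, against 1.33. The largest shift of a library by the trimmed mean was 0.097. With that shift, 52.9% of calls were higher for B against A, 44.2% for C1 against B and 44.0% for C1 against A. For C2 against C1 it was 56.1%, for C3 against C2 46.2% and for C3 against C1 50.4%. The split between higher and lower calls thus depends in part on the scaling. A pseudocount of 8 and an equal total per library were not run, because the values lack the level they need, nor was a test on whole reads, which could not be recovered. Depth limits genes of low expression most in A, B and C2 replicate 1, where a count of 0 allows 5.04 to 6.88 normalized reads.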

Other observations

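The tests of explanations in this part were chosen after the results were seen, and the bound that sets Xist against B was added after the first result of that test. The cardiomyocyte list and the lists too small to test were fixed before the data were examined. The limma differences come from the 6 comparisons above.

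Genes expressed from 1 parental copy, called imprinted, were looked at across the passages. This group of 22 genes, 19 of them measured, was put together after the values were seen, so its counts are a description with no test of the group. From C1 to C2, 7 rose and 6 fell, and from C2 to C3, 1 rose and 12 fell. Cdkn1c, an inhibitor of cell division, was at the floor in C1, had 220 normalized reads in C2 and fell by 7.03 on the log2 scale in C3. The growth factor Igf2 rose by 4.46 ± 1.27 in C2 (limma adjusted p = 0.0327) and had -7.04 ± 1.27 in C3 against C2. The long noncoding RNA Rian had -7.56 ± 0.42 in C3 against C2, beside its neighbour Meg3 with -8.08 ± 0.44. Peg3 went the other way, with -3.91 ± 0.51 in C2 against C1 and 4.13 ± 0.51 in C3 against C2. Igf2, Rian, Peg3 and Cdkn1c were not run under the alternative settings.

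Of 11 measured members of the cardiomyocyte list, 3 rose, 1 fell and 7 did not pass in C3 against C1, and the list was not called. Nppb, a natriuretic peptide, stood at 215 normalized reads in C3 and the light chain Myl7 at 45.9, and both lay under the limit of 3 reads in C1. Among lists too small to test, Mcpt8, a protease of basophils, had 62.6 normalized reads in C3 and was at the floor in C1 and C2. Pf4, a chemokine of platelets that macrophages also make, had 4116 in B and lay under the limit in C1. The lymphocyte gene Cd4, also found on myeloid cells, had 38.1 in B and lay under the limit in A, and the granulocyte protease Prtn3 had 25.8 in A and 34.4 in C1 and lay under the limit in B. The skeletal muscle actin Acta1 was higher in B than in A by 1.54 ± 0.26.

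The loss of Y-linked transcripts along the passages of one stated lineage could have several sources. Loss of the Y chromosome from 1 male population as the whole cause is argued against by Xist, which was higher in C3 than in C1 by 5.03 ± 0.89 (limma adjusted p = 0.00315). An exchange of 1 C3 library with 1 library of another type is also argued against, though an exchange of both with both of another type is not, since a C3 library differed from any library of another type by at least 1.45, in root mean square, against at most 1.06 between replicates. Descent of C3 from female and of C1 from male animals cannot be told apart from other sources: all 4 Y-linked genes lay at the floor in both C3 libraries and above it in both C1 libraries, but Xist in C3 stood at -4.83 ± 0.89 against B, or 3.51% of its level. Both B libraries held Xist and Y-linked transcripts, so B is no reference of 1 sex. Sex-linked genes differed between B and C1 already. There Xist fell by 9.86 on the log2 scale. Ddx3y, Eif2s3y and Kdm5d rose by 1.43 ± 0.31, 1.26 ± 0.23 and 1.17 ± 0.12, and Uty, at 0.86 ± 0.27, stayed under the fold threshold. In C2 the Y-linked genes had a median of -3.63 against C1, or 8.06%, while Xist did not pass there (-0.17 ± 0.89) and was higher in C3 than in C2 by 5.21 ± 0.89, which runs against a mixture of C1-like and C3-like cells in C2, and loss of the Y chromosome for that step alone, mixture with other cells and culture were not tested.

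White blood cell genes differed between the A libraries, with 47 of 50 higher in A replicate 2 and a median difference of 3.78. Depth is argued against as the source, because the depths differed by 1.14 times. Carry-over of B-type leukocytes or their RNA is a candidate explanation: the log2 ratio of A replicate 2 to B had an interquartile range of 0.882 around a median of 2.58% of the B level, while A replicate 1 lay at 0.185% with a range of 1.51, values partly set by the floor, as is the median difference, since of 22 genes with a known level 18 lay at or under the limit of 3 reads in A replicate 1 and 4 in A replicate 2. The abundant genes Emr1, Tyrobp and Ptprc had centred log2 values of 6.04, 5.38 and 6.35 in A replicate 2, of 0.83, 0.37 and 2.74 in A replicate 1, the first 2 at or under its limit, and of 12.00, 11.62 and 11.43 on average in B. The CD45-negative sort was meant to remove such cells, but its purity was not examined here. RNA carried over after the sort would not be removed by it. A difference between the animals or explants of the A libraries also stays open: Xist stood at 7.51% and 61.2% of the B level in A replicates 1 and 2, and the mean centred value of the endothelial list at 1.34 and 2.71, gaps larger than such a carry-over gives for Xist.

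Of 19 HOX genes 14 were higher in C2 and in C3 than in C1, though Hoxc6 and Hoxb4 were lower in both, and C1, C2 and C3 are passages of B-type cells by their labels. Reads near the floor are argued against for 13 of the 14 risen genes, which lay above the limit of 3 reads in both C2 libraries, with a median over the 14 of 82.4 normalized reads against a limit in C1 of at most 3.02, but for Hoxa10, at 3.08 in C2, they cannot be told apart from a rise, since the limits in C2 reach 6.12. Of the 513 genes at the floor in both C1 libraries, HOX genes among them, 115 or 22.4% rose in C2. That is short of the majority set as the mark after the results were seen, so most silent genes did not rise. Of all tested genes, 1740 of 14254 rose, but this is no fair reference for the silent genes. Genes at the floor in C1 cannot fall, and the filter kept them only because other libraries were higher. Their selection by itself thus favours a larger share of rises in C2. The comparison with all tested genes therefore cannot decide whether a wider rise among silent genes took part. Cells of another origin in the later cultures may account for the pattern, as may a change of the cells themselves, and neither was tested. The c-kit gate changed with the passage from C1 to C2, so passage and gate cannot be separated here.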
